A study of Mus musculus with 4 samples.

How the data were processed

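Genomic DNA came from 4 CD4+ T cell populations of female Balb/c mice, with 1 sample each. Per the labels' protocols, CD4+ cells were enriched magnetically, stimulated for 3 h with PMA at 10 ng/ml and ionomycin at 500 ng/ml, stained with a secretion assay for IL-17A and interferon gamma, and sorted. Naive cells had high CD45RB, Th1 cells low CD45RB with interferon gamma alone, and Th17 cells low CD45RB with IL-17A alone. Treg cells, with high CD25, were sorted first and then stimulated, so the order of the steps differed for them. Methylated fragments were captured with a MethylCap kit, libraries were made from 250 ng of captured DNA, and fragments of 250 to 350 bp were kept, again per the labels' protocols.

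The submitters' processing notes name Bowtie 0.12.7, FastQC and the mm9 build; the role of each, the treatment of reads with several matches and the calling of regions are not given in the sources used here. The deposited table gives, per region, a signal for each of the 4 libraries, which is a scaled number of reads. From the values, every naive, Th1 and Treg signal in the deposited table is a whole multiple of 1 constant per library, and 100% of values came out whole within a relative tolerance of 1e-06, so reads were recovered by division. One read was worth 0.996 in naive, 1.68 in Th1 and 0.352 in Treg. How the authors set these constants, how they chose the 10000 regions and how they ordered them is not given in the sources used here. All Th17 values in the deposited table are 0, so neither the worth of 1 Th17 read nor the depth of that library could be recovered, and no fold against Th17 is printed. All per-sample columns were matched to samples by name. The relative depth implied by the constants was 1.69 for naive and 4.77 for Treg, with Th1 as 1. Intervals are exact Poisson intervals at 95% on the reads, which cover counting error only.

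With 1 library per population there was no test between populations. A region was counted as lower or higher when the log2 ratio of the deposited values, with a pseudocount of 0.5 added to both, was at least 1 in size. The same rule had to hold in all 3 pairs for a region to differ from all other populations. An exact binomial test of the recovered reads, 2-sided, with Benjamini-Hochberg adjustment at 0.05, compared libraries; against the Th17 zeros it needed a value for 1 Th17 read, taken as 1.69, which makes the 4 constants multiply to 1. The chance of 0 Th17 reads was also computed at the depths of the Th1, naive and Treg libraries. Counting error among naive, Th1 and Treg was simulated 1000 times by sharing out each region's reads at random in proportion to the libraries' depths.

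Before the data were examined, the naming rule, the gene lists and the settings to vary were fixed. The rule names, for each comparison, the 10 regions with the largest log2 ratio, 1 per gene, ties broken by mean value and position (for all 3 others, by the smallest of the 3 ratios), the 4 members of each gene list with the largest ratio to the mean of the others, and Il17a, Il17f, Ccr6, Il23r, Ifng, Tbx21 and Foxp3 whatever their value. Some items that the rule names are not reported here. The 19 lists were Th17, Th1, Treg, Th2, Tfh, naive T cell, effector and memory, activation, T cell receptor and coreceptor, DNA methylation and chromatin, lipid and glucose metabolism, adhesion and migration, B cell, myeloid and dendritic, NK with CD8 and gamma-delta T cell, erythroid and megakaryocyte, imprinted, developmental transcription factor (homeobox, SOX, GATA and T-box), and neuronal genes. Random sets of regions matched on mean value had been planned for each list's Th17 ratio. With Th17 at 0 that ratio is set by the mean value itself, so the matching was void. In its place, the median value of each list was ranked among 10000 unmatched sets, and the Th1 to naive and Treg to naive ratios of summed values among 10000 sets matched on total reads.

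Gene names are those of the deposited table. They were joined to the lists through a GRCm38.p6 name table, used for names only, in which 0 of 5377 Ensembl identifiers matched by identifier and 5173 matched by label or synonym. Coordinates are those of the deposited table in mm9, and no genome sequence was used. Alternatives tried were thresholds of 1.5 on the log2 scale and of 1.5-fold, a pseudocount of 5, median-of-ratios scaling, a filter on the highest value, merging of adjacent regions, the exact test, list and position variants and, added after the data were examined, equal table totals. On simulated reads with 200 of 10000 regions changed, the exact test recovered 95.5% of 8-fold and 29.5% of 4-fold changes for naive, 87.5% and 10.0% for Th1, and 99.0% and 29.0% for Treg, with 1 to 7 calls among unchanged regions. The fold was applied on top of each region's real total, so changed regions held more reads than the same regions in the real data. Recovery at the real totals was not simulated, so a lack of calls does not exclude changes of these sizes. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.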

Results

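Methylated DNA was captured and sequenced from 4 populations of CD4+ T cells, with 1 library per population. The cells came from the spleen and lymph nodes of female Balb/c mice. All 4 populations were stimulated for 3 h with PMA and ionomycin, regulatory T cells after sorting and the others before it. Naive T cells carried high CD45RB. Th1 and Th17 cells had low CD45RB and secreted interferon gamma or IL-17A after stimulation with PMA and ionomycin, and regulatory T cells (Treg) were sorted by high CD25. The capture uses a methyl-CpG-binding domain protein, so the number of reads in a region rises with its methylation and with its CpG content. The table analysed here holds 10000 regions of mouse genome build mm9, with a median length of 249 bp and a range of 93 to 790 bp. Each region is assigned to a promoter, exon or intron, under 5377 Ensembl gene identifiers in all.

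The Th17 library was listed at 0 in all 10000 regions, so the table is a set of places where methylated DNA was read in at least 1 of the other populations and not in Th17 cells. The naive library held 34277 reads in these regions, the Th1 library 19548 and the Treg library 74571. Median reads per region were 3 in naive cells, 2 in Th1 cells and 7 in Treg cells. The Treg library gave the most precise values, since 1 read was worth 0.352 deposited units in it, against 0.996 in the naive library and 1.68 in the Th1 library. Of the 10000 regions, 8592 were read in all 3 of these libraries, 1401 in 2 of them and 7 in 1. All intervals given here are exact Poisson intervals at 95% and cover counting error only, and there is no replicate check on any difference.

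**Figure D1:**
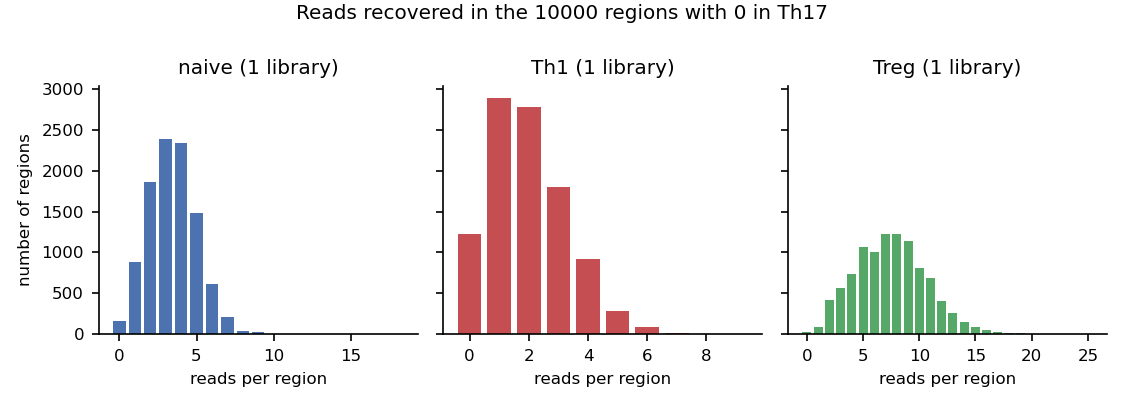
Number of regions (vertical axis) by recovered reads per region (horizontal axis) in the naive, Th1 and Treg libraries, 1 library each, over the 10000 regions listed at 0 in Th17. Medians lie at 3, 2 and 7 reads, and 161 naive, 1229 Th1 and 25 Treg regions hold no read.

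The first comparison asked which regions carried less or more methylated DNA in Th17 cells than in all 3 other populations. Il17a, the gene of the cytokine by which Th17 cells are defined, had 2 such regions that were listed at 0 in Th17 cells and read in the other 3 populations. Ccr6, a chemokine receptor of Th17 cells, had 1 region. Rora, which encodes a nuclear receptor, had 14 intronic regions on chromosome 9 between 68528972 and 69184890, of which 10 were read in all 3 populations and 4 had no Th1 read. Il17f, Il23r, Ifng, Tbx21 and Foxp3 had 0 regions in the table. The table holds 0.674% of the region numbers it spans, and how its regions were chosen is not given. The absence of a gene therefore does not show that its methylation was alike in the populations.

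The first Il17a region covered the promoter and exon 1 (chromosome 1, 20720822 to 20721221). It held 4 reads in naive cells (value 3.98, interval 1.09 to 10.2), 3 in Th1 cells (5.04, 1.04 to 14.7) and 11 in Treg cells (3.88, 1.94 to 6.94). The second, in exon 2 (20722245 to 20722432), held 5, 2 and 5 reads in naive, Th1 and Treg cells. The Ccr6 region lay in an intron on chromosome 17 (8436801 to 8436963) and held 4, 2 and 7 reads in the same order. By the mean value over naive, Th1 and Treg, the highest regions among the Th17 genes were the promoter and exon 1 of Ltb4r1, a leukotriene receptor (chromosome 14, 56384919 to 56385186), with 5 naive, 3 Th1 and 16 Treg reads, and a Rora intron (68693801 to 68694112), with 3, 6 and 7.

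**Figure D2:**
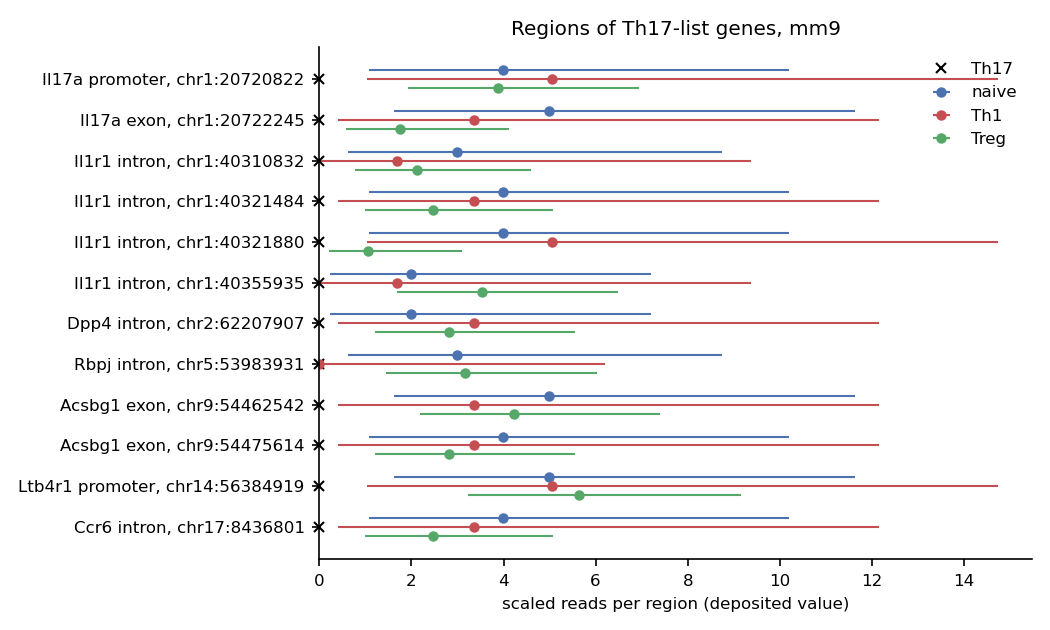
Deposited value (horizontal axis, scaled reads per region) of regions of Th17-list genes, for 1 library per population. Points are the naive, Th1 and Treg values, bars their exact Poisson 95% intervals, and crosses the Th17 value, which is 0 in every region shown; the Il17a promoter region reads 3.98, 5.04 and 3.88.

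Stat4, the transcription factor activated by the Th1-inducing cytokine receptor, was among the 10 regions with the highest smallest value over the 3 populations. Its intronic region (chromosome 1, 52098381 to 52098784) held 6 naive, 5 Th1 and 15 Treg reads, with values of 5.98, 8.40 and 5.29. The top of that ranking was an intron of C130026I21Rik (chromosome 1, 85081415 to 85081796), with 11 naive, 9 Th1 and 18 Treg reads whose mappability was not examined. Arhgap22, a GTPase-activating protein, followed with an intron on chromosome 14 (34171651 to 34172044) that held 6, 7 and 16 reads. Also in that ranking were regions of D6Mm5e, the RNA-binding protein gene Msi2, 4930465M20Rik, the ephrin receptor gene Epha6, Eng, which encodes an accessory receptor for TGF-beta, and Baiap2l2, each with 6 to 8 naive, 3 to 6 Th1 and 15 or 16 Treg reads. By the size rule, 8518 regions were lower in Th17 than in all 3 populations and 0 were higher; 8531 would pass if the 3 comparisons, which share the Th17 library, were independent. These counts restate how the table is built, because with Th17 at 0 a single naive or Th1 read, or 2 Treg reads, passes the rule.

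How much a 0 in Th17 means depends on the depth of that library, which is not given in the sources used here. If Th17 cells were methylated like the mean of the others and their library were as deep as the Th1 library, a typical region would still show no Th17 read with a chance of 19.5%, and 0 regions would pass an exact test adjusted over the table. At the naive depth that chance is 7.05%, and again 0 regions pass. At the Treg depth it is 0.162%, and 9818 regions pass over the table, but 1 passes when adjusted over all 1483567 region numbers the table spans. For the Il17a promoter region the 3 chances are 10.4%, 2.54% and 0.0136%. Without adjustment, 54 regions fall under the 0.05 limit at the Th1 depth and 2858 at the naive depth, among them the Il17a promoter region at the naive depth. The Il17a exon 2 region, with chances of 22.1% at the Th1 depth and 8.65% at the naive depth, does not. Nor does the Ccr6 region, with 19.5% and 7.05%. Genes and not regions were fixed in advance, and the table holds only regions at 0 in Th17. An unadjusted chance is therefore no test of a difference in Th17 cells, for Il17a or any other region.

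Against naive cells alone, the region with the most naive signal was the promoter of SNORD116, a small nucleolar RNA gene of an imprinted tandem array (chromosome 7, 67004473 to 67004652). It held 18 naive reads, a value of 17.9 (interval 10.6 to 28.3), against 3 Th1 and 6 Treg reads. An intron of Sfi1, which encodes a centrosome protein, followed with 12 naive reads (value 12.0). Introns of C130026I21Rik and 2610005L07Rik and promoters of 4933403O03Rik, Gm16478 and Heatr7b1 each held 11. Introns of Abcc4, a drug and nucleotide efflux pump, of the actin regulator gene Phactr2 and of Tmod2, which caps actin filaments in neurons, each held 10. In all, 9839 regions were lower in Th17 than in naive cells, each with at least 1 naive read, and 0 were higher. SNORD116 lies among near-identical copies, so its reads are uncertain in origin. The mappability of Sfi1, C130026I21Rik and the other regions named in this comparison was not examined.

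Against Th1 cells alone, the C130026I21Rik intron held the most Th1 reads, 9, with the same doubt about their origin. Regions of Gm5244, Mylk2, Ncln, Adrb3, Fabp5 and Dnajc1 held 8 Th1 reads each, a value of 13.4. Mylk2 encodes a myosin light chain kinase of skeletal muscle, Adrb3 a beta-adrenergic receptor of fat cells, Fabp5 a fatty acid-binding protein and Dnajc1 a co-chaperone. Introns of Arhgap22, of Taf1b, a subunit of an RNA polymerase I factor, and of Zfpm1, a cofactor of GATA proteins, held 7 each, a value of 11.8. The Adrb3 region was a promoter (chromosome 8, 28340249 to 28340529) and the Fabp5 region covered exon 2 (chromosome 3, 10014670 to 10015118). In all, 8771 regions were lower in Th17 than in Th1 cells and 0 were higher.

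Against Treg cells alone, exon 11 of Pdxk-ps, a pseudogene of pyridoxal kinase, held the most Treg reads, 25, with a value of 8.81 (chromosome 17, 32213303 to 32213622). The mappability of this region and of the others named in this comparison was not examined. An intron of the zinc finger gene Zfp423 followed with 23 reads. Regions of Fndc3b, Gm9144 and Tnpo1, a nuclear import receptor, held 21 each. Regions of 2610005L07Rik, the cadherin gene Cdh22, Rnf43 and Rspo4 held 20, and an intron of Stau2, an RNA transport protein, held 19. Rnf43 and Rspo4 act in opposite directions on Wnt receptors. The Tnpo1 region, in exon 7 (chromosome 13, 99640151 to 99640438), held 0 naive and 1 Th1 read, and the Rspo4 region, in exon 5 (chromosome 2, 151698728 to 151699114), 1 of each. In all, 9886 regions were lower in Th17 than in Treg cells and 0 were higher.

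The table also allowed naive, Th1 and Treg cells to be compared with each other. By the same size rule, 1125 regions were higher in naive cells than in the other 3 populations, 910 in Th1 cells and 142 in Treg cells, and 0 were lower, since nothing lies below the Th17 value of 0. Naive cells led with introns of Serpinb12, a protease inhibitor gene (7 naive reads, 0 Th1 and 0 Treg), Slc25a21 (6, 0 and 0) and App, the amyloid precursor gene (9, 0 and 1). Th1 cells led with introns of Zbbx (0 naive, 4 Th1 and 0 Treg reads), Mpped2 (0, 5 and 2) and Plcl2 (1, 6 and 2). Treg cells led with the promoter of Jph4, a junctional membrane protein gene (0, 0 and 7 reads), and with introns of the apoptosis inhibitor gene Aven (0, 0 and 6) and of Plekha7 (1, 0 and 19). These 9 regions fall outside the naming rule and were chosen by the same ranking after their values were seen.

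Counting error alone, simulated 1000 times at the deposited scaling, gave 440 regions higher in naive cells (400 to 483), 692 in Th1 cells (645 to 745) and 475 in Treg cells (432 to 516). With the libraries brought to equal table totals, the observed counts were 572, 720 and 366, and the simulated ones 366 (331 to 403), 695 (646 to 747) and 495 (458 to 536). An exact binomial test of the reads, which compares these libraries and not the cell types, with Benjamini-Hochberg adjustment, called 1 region, the SNORD116 promoter, higher in the naive library (adjusted p = 0.0130); it called 0 for Th1 and 0 for Treg. At equal table totals the exact test called 0 regions, with an adjusted p of 0.163 for SNORD116. At an unadjusted p under 0.05 it counted 610 higher and 48 lower in naive, 483 and 0 in Th1, and 33 and 747 in Treg, and at equal table totals 313 and 116, 304 and 4, and 146 and 261. No simulated counts were set against these. At the deposited scaling not 1 of the 1229 regions with no Th1 read was counted as lower, so with so few Th1 reads that direction was hardly open. In the same exact test on pairs of libraries, SNORD116 was lower in Treg than in naive (adjusted p = 0.00794) and no other region passed, but at equal table totals its adjusted p was 0.150 and 0 regions passed. The mean value in Treg was below that in naive by a log2 ratio of -0.38 and below that in Th1 by -0.32, while Th1 and naive differed by -0.06.

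The gene lists fixed before the data were examined were counted next. A gene passed when any of its regions was lower in Th17 than in all 3 others. With Th17 at 0 throughout, this depends only on reads in the other libraries, and 8518 of the 10000 regions, 85.2%, meet it. The passing counts of the lists therefore say nothing about Th17. Of 32 Th17 genes, 9 had a region in the table and 8 had one lower in Th17 than in all 3 others; among the 9 were Il17a, Rora, Ccr6, Ltb4r1, Il1r1, Dpp4, Rbpj and the acyl-CoA synthetase gene Acsbg1. The 27 regions of these genes had mean values of 3.98 in naive cells (interval 3.27 to 4.81), 2.99 in Th1 cells (2.20 to 3.96) and 2.72 in Treg cells (2.36 to 3.11). Over the whole table the means were 3.41, 3.29 and 2.63, in the same order. Rora alone held 14 of the 27 regions, so the list means rest largely on that gene. Of 25 Th1 genes, 5 had a region and all 5 passed in all 3 comparisons: Stat4, the protease gene Gzmb (exon 4), Il18r1, Runx3 and Il27ra. Of 26 Treg genes, 4 had a region and 3 passed, Itgae, Tnfrsf9 and Socs2, while Nrp1 had no Th1 read. Th2 genes gave 3 of 15 (Epas1, Il1rl1 and Plcd1) and Tfh genes 4 of 14 (Pou2af1, Tox, Tox2 and Sh2d1a), all passing. For comparison, 4834 of 21896 protein-coding genes, 22.1%, had a region.

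Genes of naive T cells had regions in 8 of 25 cases, led by Actn1, Igf1r, Txk and Pdk1, and 7 passed in all 3 comparisons. Foxp1, which holds T cells in the naive state, was the exception, with 0 naive, 2 Th1 and 13 Treg reads in an intron (chromosome 6, 98934698 to 98934985). Effector and memory genes gave 6 of 27, with 5 passing, led by Runx2, S100a11, Prdm1 and Il18r1. Activation genes gave 6 of 32, all passing, led by Nfatc2, Ccl1, Nfkb1 and Nfatc1. The 5 regions assigned to Ccl1 lay between 82003367 and 82097882 on chromosome 11, and whether they lie within the gene was not checked. Genes of DNA methylation and chromatin gave 10 of 33, with 9 passing, led by the methyl-CpG reader gene Mbd2, the DNA methyltransferase gene Dnmt3a (exon 19), Uhrf2 and Dnmt1. Lipid and glucose metabolism gave 10 of 32, with 8 passing, including Rptor, Slc2a3 and Hk1. Adhesion and migration genes gave 7 of 28, all passing, led by Itga2, Selplg, Itga1 and Itgal.

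Of 28 T cell receptor and coreceptor genes, 6 had a region: the signalling adaptor gene Lcp2, the costimulatory receptor gene Cd28, the kinase gene Fyn, Cd5, Plcg1 and Runx1. Their mean value was 6.72 in the Th1 library (interval 4.31 to 10.0, 24 reads) and 2.49 in the naive library (1.39 to 4.11, 15 reads), a log2 ratio of 1.43. That ratio lay at percentile 99.8 of 10000 random sets of regions with the same reads, and the median value of the 6 regions at percentile 99.0 of unmatched sets. The members differed: naive and Th1 reads were 1 and 6 in Lcp2, 1 and 5 in Cd5 (exon 5), 1 and 4 in Fyn, 3 and 4 in Plcg1 and 4 and 4 in Cd28, but 5 and 1 in Runx1, which lay the other way. Of 54 such percentiles computed over the lists, 3 lay outside the central 95%, among them both of these, against 2.7 by chance alone, so no list is shown to stand apart.

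Markers of other cells were present as well. B cell markers had regions in 7 of 16 cases, 6 of them passing, including Ebf1, Blnk and Blk. Myeloid and dendritic markers gave 4 of 22 (Mpo, Sfpi1, Csf3r and Flt3), all passing, and markers of NK, CD8 and gamma-delta T cells 5 of 18, of which 3 passed (Zbtb16, Txk and Blk) while Gzmk and Sox13 had no Th1 read; Txk and Blk also stand in other lists. Erythroid and megakaryocyte markers gave 0 of 13. Imprinted genes gave 3 of 28 (Airn, Grb10 and Igf2r) and a list of developmental transcription factors, mainly homeobox, paired-box and SOX genes, 6 of 37, with 5 passing. These were Meis1, Meis2 and Pax2, the GATA genes Gata4 and Gata6, and the T-box gene Tbx5, with no SOX gene of the list among them. Neuronal genes gave 26 of 28, all passing, with 138 regions led by the splicing regulator gene Rbfox1 and the glutamate receptor genes Grin2b and Gria2. The median value of these 138 regions lay at percentile 1.13 of random sets. Gene length was not taken into account in any list's share, and Auts2 of the neuronal list alone held 21 regions over 1020 kb. The neuronal share is thus not shown to reflect the kind of gene. In Fisher's exact test, 2-sided, of genes lower in Th17 than all 3 against the other genes in the table, 0 of the 18 lists with a region passed after Benjamini-Hochberg adjustment and 0 had an unadjusted p under 0.05. With Th17 at 0 throughout, the split depends only on reads in the other libraries, so this test says nothing about Th17.

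**Figure D3:**
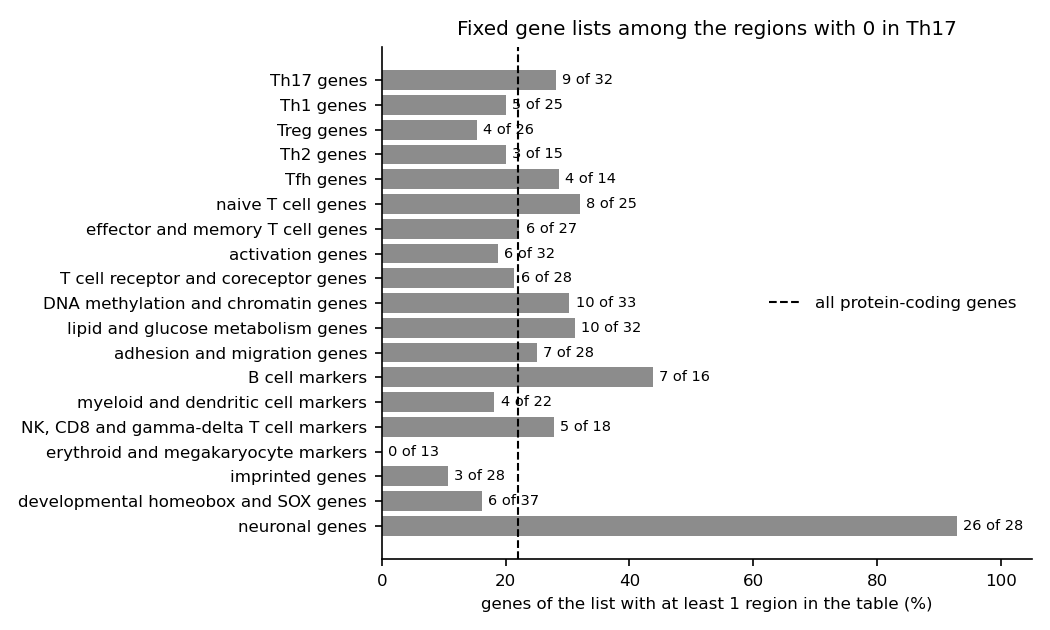
Share of the genes of each fixed list with at least 1 region among the 10000 listed at 0 in Th17 (horizontal axis, percent), with the counts beside each bar. The dashed line marks 22.1%, the share of all protein-coding genes. Th17 genes stand at 9 of 32 and neuronal genes at 26 of 28, with no account of gene length.

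The last comparison asked where in the genome the regions lay. Introns held 7865 regions, 78.7% (Wilson interval 77.8% to 79.4%), exons 1658, 16.6%, and promoters 477, 4.77% (4.37% to 5.21%). The genes with the most regions were Fgfr2, a fibroblast growth factor receptor gene, with 39, AC114005.5 with 27, Park2, a ubiquitin ligase gene, with 26 and the cell adhesion gene Sdk1 with 25, as the deposited table assigns them. The Fgfr2 regions spanned 2886 kb and those of AC114005.5 3829 kb, against 929 kb for Park2 and 941 kb for Sdk1. Whether these regions lie within the genes they are assigned to was not checked. Of 5377 genes, 3434 had 1 region and 57 had 10 or more. The planned test of regions lower in Th17 than all 3 others against the rest gave adjusted p = 0.171 for introns, 0.112 for exons and 0.553 for promoters (Fisher's exact test, 2-sided), but with Th17 at 0 throughout the split is set by the reads in the other libraries, mainly Th1, and says nothing about Th17. Chromosome X held 200 regions, 4.87 per 1000 region numbers, against 6.83 on autosomes, a ratio of 0.713 (Fisher's exact test, 2-sided, p = 6.4e-07). The densest chromosomes were 11, with 8.16, and 2, with 7.97, and the sparsest autosomes were 3, with 5.54, and 13, with 5.61. The p for chromosome X is against all autosomes pooled, so it does not measure the spread between chromosomes. Gene density was not taken into account. These tests run over regions, which are not replicates.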

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

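The setting with equal table totals was chosen after the data were examined, and the others before. The counts of regions lower in Th17 than naive, Th1, Treg and all 3 stayed within 1.5 times their values of 9839, 8771, 9886 and 8518 under both other thresholds, median-of-ratios scaling, merging of adjacent regions and equal table totals; with Th17 at 0 scaling can hardly move them, so this says little about stability. A pseudocount of 5 lowered them to 888, 3100, 186 and 11, since it exceeds most values. The filter on the highest value left 5038, 4669, 5057 and 4509, by removing regions. The exact binomial test, with a Th17 read worth 1.69, called 0, 0, 0 and 0 of them. That assumed worth is close to the 1.68 of a Th1 read. Against the mean of the other populations at that depth, the lowest chance of 0 Th17 reads in any region was 0.869%. No region passed there after adjustment over the table, but 9818 passed at the Treg depth. The 0 calls therefore rest on the assumed depth, and this setting does not test the counts. Counts of regions higher in naive, Th1 or Treg than in the other 3, which were 1125, 910 and 142, became 400, 276 and 24 at a log2 threshold of 1.5 and 2115, 2105 and 423 at 1.5-fold, as the rule alone requires. They became 28, 53 and 0 with a pseudocount of 5, 716, 573 and 323 with median-of-ratios scaling, and 1, 0 and 0 in the exact binomial test. The Treg count was 33 under the filter on the highest value and 366 at equal table totals, where the naive count was 572. The filter removes regions whose highest value is low. Equal table totals lower the naive values, whose mean was 3.41, and raise the Treg values, whose mean was 2.63. These shifts therefore follow from the settings. Merging adjacent regions kept all 7 counts within 1.5 times. No gene list passed Fisher's exact test in any setting. The limit to promoters and gene bodies removed no region, because every region carries a promoter, exon or intron label. That setting therefore tested nothing, and whether the labels place each region within its gene was not checked. Promoters made up 4.72% of regions lower than all 3, 4.73% at a log2 threshold of 1.5 and 4.54% on autosomes. A stricter limit on the authors' p-values was not run, because no p-values were analysed here. No paired analysis was possible because each population has 1 library. Depth limits every value: the Th1 library held a median of 2 reads per region, and the depth of the Th17 library is not given in the sources used here.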

Other observations

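All tests and gene families in this part were chosen after the results were seen. Some gene families were counted among the regions listed at 0 in Th17, against 22.1% of all protein-coding genes, with no test of enrichment and no account of gene length. Ionotropic glutamate receptors, which carry fast excitatory signals between neurons, had regions in 16 of 18 genes, voltage-gated calcium channels with their auxiliary subunits in 22 of 26 and cadherins, which join cells to each other, in 16 of 23. Genes of the Kcn series, which encode potassium channels of all kinds and their auxiliary subunits, had regions in 40 of 94 genes, ephrin receptors in 8 of 14 and semaphorins with plexins in 11 of 29. Zinc finger genes of the Zfp series had regions in 53 of 367 and olfactory receptor genes in 28 of 1106, 2.53%. Several genes held clusters of regions across their introns, among them Rbms3, an RNA-binding protein gene, with 23 regions over 996 kb of chromosome 9, Cdh13 with 21 over 913 kb of chromosome 8 and Cdh4 with 20 over 436 kb of chromosome 2. Zfp362, a zinc finger gene with an intronic region on chromosome 4 (128462614 to 128462965), was singled out after its values were seen; it held 5 naive, 4 Th1 and 9 Treg reads.

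Of the 10000 regions listed at 0 in Th17, 158 pairs had adjacent region numbers, against a mean of 104 pairs (SD 11.6, highest 130) at each distance from 11 to 50 numbers. The mean was 120.3 pairs at 2 to 10 numbers, where the highest was 137, and 82.5 at the farthest distances, up to 200 numbers, so counts fell slowly with distance. It stays open whether independent counting error in the Th17 library is the whole cause, because the regions hold reads in the other libraries and neighbours can share fragments and local coverage there. Of the adjacent pairs, 69 lay within 350 bp of each other and 89 farther apart. A loss of methylation in Th17 cells over stretches longer than 1 region is a candidate explanation that these values neither require nor exclude.

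Of the regions higher in 1 population, the naive count alone exceeded counting error at both scalings. At equal table totals it was 572 against 331 to 403 simulated, which argues against counting error alone, as simulated, as the whole cause of the naive count. The simulation did not model how the 10000 regions were chosen, so selection acting on counting error is not excluded. The Th1 count, 720 against 646 to 747, lay within counting error there but above it at the deposited scaling, so for Th1 the scaling keeps this open, and the Treg count, 366 against 458 to 536, lay below it at both scalings, so no excess was seen. Methylation differences between the populations, differences in capture between libraries and the way the 10000 regions were chosen could each contribute and were not tested. The regions with no naive read were fewer than simulated at equal table totals, 161 against 302, as were those with no Th1 read, 1229 against 1386, while those with no Treg read were more, 25 against 3.55.

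The paired Il17a regions and the 4 Il1r1 regions raised the hypothesis that lower methylation at Th17 genes may extend over neighbouring regions. Consecutive regions of 1 gene lay within 10 region numbers in 5 of 18 pairs of the Th17 list, 27.8%, and in 1103 of 4595 pairs of other genes, 24.0%. Without Il17a and Il1r1, whose pairs prompted the hypothesis, the share was 2 of 14, 14.3% (Fisher's exact test against other genes, 2-sided, p = 0.540). Of these 14 pairs, 13 lay in Rora alone, so the test says little about other Th17 genes and leaves the hypothesis open, and a p that misses the threshold does not show that the shares are equal.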
